A study of Homo sapiens with 36 samples.

How the data were processed

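The data were 1 table of 36 arrays hybridised with total RNA of primary human ALL cells, numbered here as replicates 1 to 36. Per the labels, the authors computed each probe set's signal intensity with the Affymetrix Statistical algorithm and multiplied each array by a scaling factor that sets the trimmed mean of all probe sets to the target of 500. The deposited values were these intensities on a linear scale. The table bears this out: with 2% of the probe sets left out at each end, the mean signal of each array was 499.9. The labels also give the scaling factor of each array, between 7.67 and 74.2 with a median of 28.2, and a background and a noise value. Noise multiplied by the scaling factor lay between 21.9 and 92.6 signal units, so signals near or under 100 were close to the noise of some arrays. Detection calls were not used here. How resistance was measured is not given in the sources used here, and drug-sensitive samples were not analysed here. The number of arrays limits the precision. Nothing in the labels says whether the 36 samples came from separate donors, so p-values of correlations and slopes measure the spread between these samples. The p-values of the list tests set gene lists against random gene lists on the same arrays, and do not measure a spread between samples.

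Of 22283 probe sets, 19071 had 1 gene symbol in the platform annotation, 1043 had several and 2169 had none here, of which 68 were control probe sets. Through the Entrez identifier 19059 of the 1-symbol probe sets were matched to the RefSeq gene table, and 0 symbols changed. Probe sets with several symbols or none, control probe sets, XIST, TSIX and Y-linked genes were left out of all tests. Signals were floored at 100 and converted to log2. Probe sets with a signal of at least 200 on at least 4 of the 36 arrays were kept, and of several probe sets of a gene the one with the highest mean log2 signal was used, which left 10350 genes. Folds against a value at the floor are lower bounds.

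The choices in this paragraph were made before the data were examined. There were 25 gene lists: B precursor, T lineage, cytotoxic lymphocyte, monocyte, neutrophil granule, erythroid, platelet, plasma cell, progenitor, mitosis, DNA replication, tubulin, microtubule-associated, actin cytoskeleton, drug efflux, BCL2 family, caspase and IAP (inhibitors of apoptosis), ribosomal protein, glycolysis, oxidative phosphorylation, interferon response, immediate early, heat shock, MHC class II and subtype-associated. For each list the mean pairwise Pearson correlation of its measured members, and the median of their SDs, were set against 10000 random lists of the same size matched on mean level in 20 bins, with 1-sided permutation p-values adjusted by Benjamini-Hochberg over the lists. A list score was the mean of its members' gene-centred log2 signals. Scores of pairs of lists were correlated with 2-sided permutation tests (100000 permutations), adjusted over all pairs, and r was recomputed without the 2 arrays farthest from the median of the first list. A score was taken to split the samples where the largest gap between neighbouring values, with at least 3 arrays on each side, exceeded 20% of the range; no pooled correlation of that score with another and no pooled regression on it was then given, while the list tests were still made over all arrays. Every gene was regressed on the mitosis, monocyte and T lineage scores, scaled to an SD of 1 with list members left out, and on log2 scaling factor, with limma (lmFit, and eBayes with trend), at a Benjamini-Hochberg adjusted p under 0.05. Slopes are given with their standard errors.

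The genes named were those with the 10 highest means, the 25 largest SDs, the 2 highest means and 2 largest SDs in each list, the 10 largest positive and negative slopes of each association, the 10 strongest pairs of lists, and 10 fixed genes tied to the drug, to cell death, to cycling or to lineage. Of the 10 fixed genes 1 is not reported here. Not named were classical polymorphic HLA genes and 5 genes whose levels follow common inherited variants. Other members of the lists and further genes past a threshold were named after their values were seen.

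Other settings chosen beforehand were a floor of 32 or 200, no filter, a filter of 500 on at least 9 arrays, quantile normalization between arrays, the mean of all probe sets of a gene, log2 scaling factor or the lot batch line as a covariate, leaving out arrays with a scaling factor over 50, Spearman in place of Pearson, random lists matched also on SD, and robust moderation in limma. Added after seeing the data were fits within the arrays below the T lineage gap, a fit of the monocyte score within those of them below a gap in the neutrophil granule score, fits with the side of the T lineage gap as a covariate, exact permutation tests within the 7 arrays above it, and fits without each array in turn. Quantile normalization moved the median gene by 0.0025 on the log2 scale.

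The methods were tested on simulated data with the real gene means. In the list and limma tests the simulated genes varied independently apart from what was planted, and the limma data were not floored. False calls counted there therefore do not cover genes that vary together. In the list test on 10350 genes, a shared factor giving a pairwise correlation of 0.1 was recovered in 12 of 13 lists, with 0 of the 12 other lists called. A correlation of 0.05 was recovered in 8 of 13, and with nothing planted 1 of these 13 was called. At a correlation of 0.2 all 13 were recovered and 1 of the 12 others was called. A spread raised 1.5-fold, planted along with the correlation of 0.1, was recovered in 11 of 13, with 1 of 12 others called. In the limma test, slopes of 0.5 were recovered in 71.6% of changed genes for the mitosis score (10329 genes) and 62.7% for the T lineage score (10328 genes, 29 arrays), and slopes of 1 in 100% of them for both. Slopes of 0.25 were recovered in only 8.96% and 14.9%, and 10 and 3 unchanged genes were called. In the test of pairs, 3 of 30 planted correlations of 0.4, 21 of 30 of 0.6 and 30 of 30 of 0.8 were called, with 1, 2 and 4 of 1350 other pairs called. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.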

Results

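RNA of 36 samples of primary acute lymphoblastic leukaemia (ALL) cells was measured on 1 oligonucleotide array each. ALL is a cancer of immature B or T lymphocytes. The series title describes the samples as resistant to VCR, the customary abbreviation of vincristine, a plant alkaloid that binds tubulin and stops cells in mitosis. All 36 samples formed 1 group in the labels, so no difference between groups was tested, and no value given here measures resistance. The question addressed was which genes and gene groups varied between these samples, and which of them varied together. The median signal of an array lay between 188.5 and 256.6, and between 27% and 32.6% of the probe sets of an array lay under the floor of 100. The highest correlation of any array with another was 0.915, so no pair of arrays held the same values.

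Genes with large SDs between samples included markers of lymphoid lineage and of myeloid cells. CD3D, a chain of the T-cell receptor complex, had a mean log2 signal of 9.47 ± 2.73 (SD, n = 36), and its highest signal of 35057 was at least 350.6-fold above its lowest. LCK, the kinase that starts T-cell receptor signalling, had a mean of 9.41 ± 2.54, and MAL, a membrane protein of T cells, one of 8.75 ± 2.15 (SD, n = 36). Among B-cell genes, VPREB1, a part of the surrogate light chain of precursor B cells, reached 9.92 ± 2.12, MME, which encodes the surface marker CD10, 8.85 ± 2.04, CD9 10.49 ± 2.35 and TCF4 11.26 ± 2.13 (SD, n = 36). HLA-DRA, the alpha chain of a class II antigen-presenting molecule, averaged 13.72 ± 2.25, with a signal of at least 200 on 35 of the 36 arrays. The calcium-binding proteins S100A8 and S100A9, abundant in monocytes and neutrophils, averaged 9.94 ± 2.56 and 9.09 ± 2.16, and the lysozyme gene LYZ 8.65 ± 2.09 (SD, n = 36). Also among the 25 largest SDs were the neuropeptide gene NPY (11.17 ± 2.49), the growth factor genes HBEGF (11.39 ± 2.43) and PDGFA (9.13 ± 2.15), the transcription factor genes MEF2C (10.05 ± 2.25), HLX (10.03 ± 2.18) and KLF4 (11.67 ± 2.05), and ADM, the gene of the vessel-widening peptide adrenomedullin (10.53 ± 2.18).

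The T lineage genes fell into separate clusters of arrays. The T lineage score, the mean gene-centred log2 signal of 20 T-cell genes, lay between -1.14 and 0.04 on 29 arrays and between 1.98 and 3.11 on the other 7. The gap took 45.6% of the range, above the 20% set beforehand. The 7 arrays were also the 7 with the lowest scores of the B precursor genes (-2.33 to -1.54) and the 7 with the lowest scores of the MHC class II genes. Relations between genes were therefore recomputed within the 29 arrays below the gap. The labels name no lineage for any sample. The 3'/5' signal ratio of ACTB, a measure of RNA or cDNA length, was between 1.68 and 3.96 on the 7 arrays and between 1.06 and 3.26 on the 29. A line headed as a lot batch, with no value, was present in the labels of 26 of the arrays below the gap and absent from those of the other 3 and of all 7 above it.

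**Figure D1:**
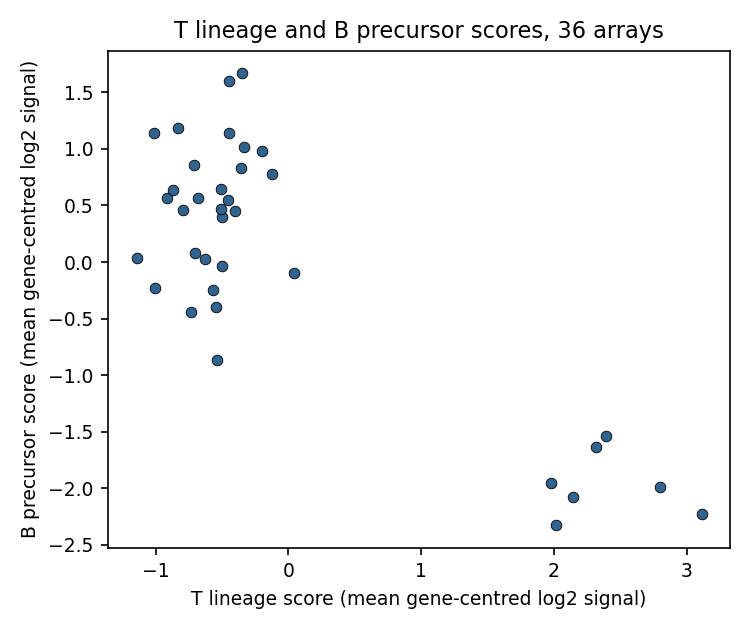
Each point is 1 of the 36 arrays. The x axis gives the T lineage score and the y axis the B precursor score, both as mean gene-centred log2 signal; 29 arrays lie between -1.14 and 0.04 on the x axis and 7 between 1.98 and 3.11.

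The tubulin genes, which encode the protein that vincristine binds, were measured with 14 of 16 members. Signals of at least 200 were present on all 36 arrays for the probe sets assigned to TUBA1A (13.47 ± 0.89), TUBA1B (15.04 ± 0.43), TUBA1C (15.11 ± 0.39), TUBB (13.89 ± 0.45), TUBB3 (11.92 ± 0.55), TUBB4B (13.30 ± 0.61) and TUBA4A (10.64 ± 1.14; log2, SD, n = 36). Whether each probe set reads a single tubulin gene was not tested. Levels and correlations given for tubulin genes are therefore those of the probe sets. The class II beta tubulin gene TUBB2A (11.15 ± 1.46) and the class V gene TUBB6 (8.81 ± 1.49) varied most within this list, and TUBB6 reached 200 on 28 arrays. TUBA8 reached 200 on 5 arrays and TUBB4A on 10. The mean pairwise correlation of the tubulin genes was 0.0668 against a median of 0.00136 for random lists (adjusted p = 0.0323, one-sided permutation test against 10000 random lists, Benjamini-Hochberg over 25 lists). The tubulin genes no longer passed without a filter (0.0469), with the lot batch line as a covariate (0.0475), with Spearman correlations (0.0525) or without arrays of a scaling factor over 50 (0.0548). The spread of the tubulin genes did not exceed that of random lists (median SD 0.611 against 0.627, adjusted p = 0.694).

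Among genes of proteins that bind, fold or regulate microtubules, all 22 were measured and their members did not correlate beyond random lists (mean r 0.0237, adjusted p = 0.120). MAPRE1, which tracks growing microtubule ends, averaged 12.40 ± 0.28, MAP4, a stabilising protein, 9.24 ± 0.59, and the destabilising protein gene STMN1 10.23 ± 0.73 (log2, SD, n = 36). TBCD, a tubulin-folding cofactor, had the largest SD of the list (8.74 ± 1.66). The drug efflux genes did not correlate beyond random lists either (8 members, mean r 0.0601, adjusted p = 0.117), and their median SD was 0.648 (adjusted p = 0.520). ABCB1, which encodes the efflux pump P-glycoprotein that transports vinca alkaloids, averaged 7.91 ± 0.59 and reached 200 on 27 of the 36 arrays, with a highest signal of 522. ABCC1, another transporter of vinca alkaloids, averaged 10.34 ± 0.87 and lay between 449 and 5158. ABCC5 averaged 8.74 ± 0.67 and MVP 8.08 ± 0.83; ABCG2 reached 200 on 24 arrays and ABCC4 on 4. A level of 1 probe set cannot be set against that of another, since probe sets differ in how brightly they respond.

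**Figure D2:**
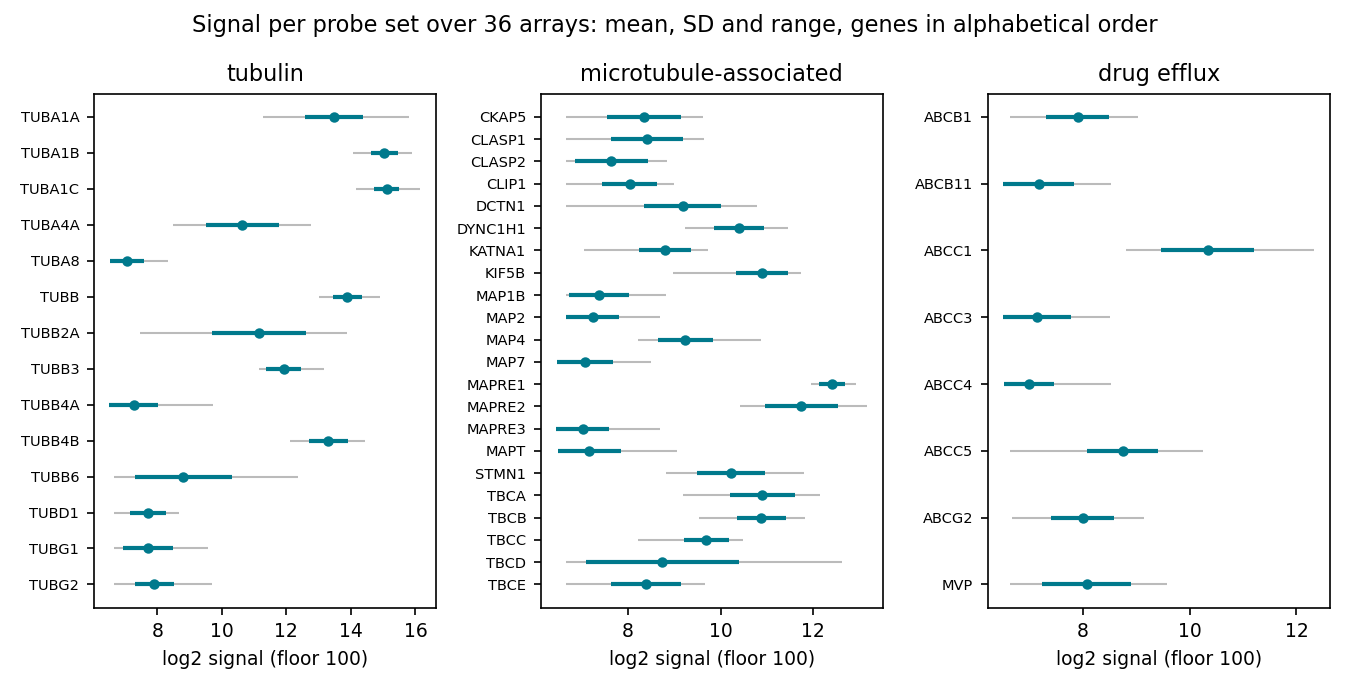
Points give the mean log2 signal of each measured member of the tubulin, microtubule-associated and drug efflux lists over 36 arrays, thick bars 1 SD and thin lines the range, after a floor of 100. TUBB6, with an SD of 1.49, and TBCD, with an SD of 1.66, span much of their axes, and positions of different genes are not comparable.

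Neither list of cell death genes passed a list test over the 36 arrays. In the BCL2 family list, with 15 members measured, the mean pairwise correlation was 0.00398 (adjusted p = 0.592) and the median SD 0.821 (adjusted p = 0.056); within the 29 arrays its median SD of 0.811 did pass (adjusted p = 0.0316). MCL1, an inhibitor of cell death, averaged 13.33 ± 0.70 and BCL2 8.71 ± 0.60, both with signals of at least 200 on all 36 arrays (log2, SD, n = 36). Averaging all their probe sets moved these means to 10.41 and 7.99, so the levels depend on the probe set read. PMAIP1, the cell-death inducer NOXA, averaged 12.04 ± 1.12. BCL2A1 (8.92 ± 1.68) and BIK (7.57 ± 1.42) had the largest SDs of that list. The caspase and IAP list gave a mean r of 0.047 (12 members, adjusted p = 0.117) and a median SD of 0.653 (adjusted p = 0.756). In it, DIABLO averaged 10.29 ± 0.41 and CASP8, the caspase of death receptors, 10.06 ± 1.04.

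Ribosomal protein genes were among those named for their mean signal. RPS10 averaged 16.14 ± 0.33, RPS23 16.12 ± 0.34, RPL41 16.08 ± 0.34, the elongation factor gene EEF1A1 16.10 ± 0.33 and TPT1 16.29 ± 0.39 (log2, SD, n = 36). A probe set assigned to HUWE1, a ubiquitin ligase, averaged 16.52 ± 0.35. The other 3 probe sets of HUWE1 correlated with it at -0.08 to 0.15. Those averaging 7.26 and 6.70 lay close to the floor, where a correlation says little, and that averaging 10.83 gave -0.08. The signal was therefore not taken as a level of HUWE1.

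In 17 of the 25 lists the members correlated across the 36 arrays more than random lists matched on level (adjusted p under 0.05, one-sided permutation test). The highest mean pairwise r were those of the T lineage (0.568), neutrophil granule (0.554), ribosomal protein (0.542), MHC class II (0.529) and erythroid (0.493) genes. DNA replication genes followed at 0.461, B precursor genes at 0.417, mitosis genes at 0.347, oxidative phosphorylation genes at 0.324 and heat shock genes at 0.320. Lower values that still passed were those of the monocyte (0.248), interferon response (0.229), immediate early (0.216), glycolysis (0.165), cytotoxic lymphocyte (0.160) and actin cytoskeleton (0.151) lists. The adjusted p was 0.000167 for 15 of these lists, the smallest that 10000 random lists gave, and 0.000625 for the cytotoxic lymphocyte genes. The ribosomal protein probe sets were bright, with a median of their mean log2 signals of 15.2. Whether a property shared by bright probe sets enters their correlation was not tested. The platelet (-0.00684, adjusted p = 0.734), plasma cell (-0.0126, adjusted p = 0.673), progenitor (-0.00545, adjusted p = 0.747) and subtype-associated (-0.0245, adjusted p = 0.923) lists did not pass. Among the 29 arrays below the T lineage gap, 16 lists passed. There the T lineage genes no longer did, with a mean r of 0.0387, while the value of the B precursor genes was 0.153 and that of the MHC class II genes 0.401.

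**Figure D3:**
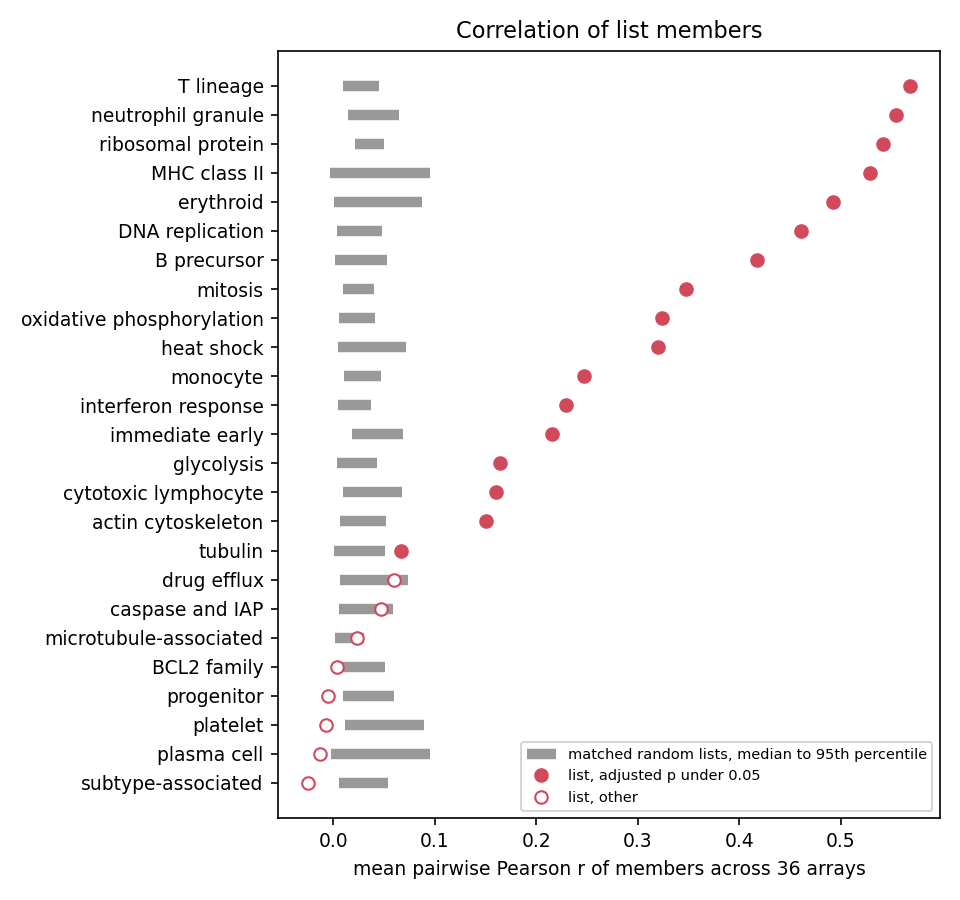
Points give the mean pairwise Pearson r of the measured members of each of the 25 lists across 36 arrays, filled where the adjusted p was under 0.05; grey bars run from the median to the 95th percentile of 10000 matched random lists. The T lineage list lies highest at 0.568 and the subtype-associated list lowest at -0.0245.

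Spread between samples exceeded that of matched random lists in 12 lists. The B precursor genes had a median SD of 1.59 against 0.65 for random lists, the MHC class II genes 1.52 against 0.64 and the T lineage genes 1.51 against 0.66 (adjusted p = 0.000417 each, permutation test). Within the 29 arrays these values were 1.11 against 0.60 (adjusted p = 0.000625), 0.72 against 0.62 (adjusted p = 0.201, not passing) and 0.84 against 0.64 (adjusted p = 0.000833). CD79A, a part of the B-cell receptor, averaged 11.97 ± 1.71, PAX5, the factor that commits cells to the B lineage, 10.65 ± 1.57, and CD74, the chaperone of class II molecules, 13.92 ± 1.81 (log2, SD, n = 36). The erythroid (median SD 1.24, adjusted p = 0.000714), cytotoxic lymphocyte (1.09), neutrophil granule (1.09), monocyte (0.847, adjusted p = 0.00611) and progenitor (0.933, adjusted p = 0.00187) lists also passed, of which the cytotoxic lymphocyte list did not within the 29 arrays (0.776, adjusted p = 0.0863). HBB, a haemoglobin chain, averaged 15.19 ± 1.42, NKG7, a granule protein of cytotoxic cells, 8.73 ± 1.53, and SPINK2 of the progenitor list 7.64 ± 1.78. Response genes passed as well, with immediate early genes at 1.04, heat shock genes at 0.887 (adjusted p = 0.00773) and interferon response genes at 0.820 (adjusted p = 0.00773). NR4A2 averaged 11.22 ± 1.65, the chemokine gene CXCL8 10.68 ± 1.94, the small heat shock protein gene HSPB1 11.94 ± 1.76 and IFITM1 11.30 ± 1.64. The subtype-associated genes, each known to be high in single genetic subtypes of ALL, passed with a median SD of 0.774 (adjusted p = 0.0279); TCFL5 averaged 9.23 ± 1.88 and LGALS1 8.98 ± 1.82. Beside the BCL2 family, tubulin, drug efflux and caspase and IAP lists given above, lists that did not pass were mitosis (0.770, adjusted p = 0.0668), actin cytoskeleton (0.723, adjusted p = 0.0668), glycolysis (0.735, adjusted p = 0.0686) and DNA replication (0.752, adjusted p = 0.116). The platelet (0.665, adjusted p = 0.29), plasma cell (0.726, adjusted p = 0.29), microtubule-associated (0.633, adjusted p = 0.653) and oxidative phosphorylation (0.580, adjusted p = 0.694) lists did not pass either. Ribosomal protein genes had a median SD of 0.363, below the 0.578 of random lists, and did not pass.

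Cycling genes rose and fell together. MKI67, a marker of cycling cells, averaged 9.34 ± 0.56 (log2, SD, n = 36). The scores of the mitosis and DNA replication genes correlated across the 36 arrays with r = 0.87 and rho = 0.88 (permutation p = 1e-05 each, the smallest 100000 permutations give; adjusted p = 0.00092 for r and 0.00138 for rho over 276 pairs), and r was 0.84 without the 2 farthest arrays. In the 29 arrays below the T lineage gap r was 0.83 and rho 0.80 (permutation p = 1e-05 each, adjusted p = 0.00276 each). Monocyte and neutrophil granule scores correlated with r = 0.84 and rho = 0.82 over 36 arrays (permutation p = 1e-05 each, adjusted p = 0.00092 and 0.00138; r = 0.79 without the 2 farthest). Because the granule score fell into clusters of 25 and 4 within those 29 arrays, r was taken within the 25, where it was 0.65 and rho 0.65 (permutation p = 0.00042 and 0.00064), and 0.42 without the 2 farthest. The B precursor and microtubule-associated scores correlated within the 29 arrays with r = 0.71 and rho = 0.68 (permutation p = 2e-05 and 0.00013, adjusted p = 0.00276 and 0.0179; r = 0.64 without the 2 farthest). Within the 7 arrays above the gap that r was 0.23 and rho 0.29 (exact permutation p = 0.591 and 0.556). Over the 36 arrays, the planned test, this pair was not among the 12 that passed. The 7 arrays had the lowest B precursor scores (-2.33 to -1.54), but microtubule-associated scores of 0.06 to 0.37, against -0.47 to 0.24 on the 29. In the 29 arrays the B precursor and microtubule-associated scores had r = -0.36 and -0.48 with log2 scaling factor (permutation p = 0.0534 and 0.00816, adjusted p = 0.571 and 0.418). The correlation of this pair with that factor removed was not computed within the 29.

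Oxidative phosphorylation genes entered 6 of the 12 pairs that passed over the 36 arrays, a number that became 28, 21 and 23 without replicates 2, 3 and 14 in turn. Their score correlated with those of DNA replication (r = 0.65, rho = 0.62, permutation p = 3e-05 and 6e-05, adjusted p = 0.00166 and 0.00552), mitosis (r = 0.57, rho = 0.55, permutation p = 0.00025 and 0.00069, adjusted p = 0.00986 and 0.0255) and glycolysis (r = 0.57, rho = 0.55, permutation p = 0.00021 and 0.00074, adjusted p = 0.00966 and 0.0255). Against the microtubule-associated genes r was 0.56 and rho 0.55 (permutation p = 0.00039 and 0.0006, adjusted p = 0.0135 and 0.0255). The relation to the immediate early genes, which stress and handling induce within minutes, was negative (r = -0.63, rho = -0.53, permutation p = 2e-05 and 0.00101, adjusted p = 0.00138 and 0.0279). Without the 2 farthest arrays these 5 values of r were 0.55, 0.48, 0.48, 0.50 and -0.54. In the 29 arrays they were 0.47, 0.41, 0.41, 0.44 and -0.46, with adjusted p between 0.27 and 0.312 over 276 pairs, so none of the 5 passed there. Actin cytoskeleton and glycolysis scores correlated with r = 0.54 and rho = 0.53 over 36 arrays (permutation p = 0.00053 and 0.00089, adjusted p = 0.016 and 0.0273; r = 0.52 without the 2 farthest), against 0.46 within the 29 (adjusted p = 0.27). Monocyte and actin cytoskeleton scores gave r = 0.53 and rho = 0.42 (permutation p = 0.00058 and 0.0111, adjusted p = 0.016 and 0.133; r = 0.40 without the 2 farthest), against 0.49 within the 29 (adjusted p = 0.223).

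MHC class II genes entered the remaining 3 pairs. No pooled value is given for the pair of B precursor and MHC class II genes, since the 7 arrays stood apart in both. Their r was 0.24 and rho 0.25 within the 29 arrays (permutation p = 0.209 and 0.191) and -0.14 and 0.07 within the 7 (exact permutation p = 0.758 and 0.906). The MHC class II score correlated within the 29 arrays at -0.02 with the oxidative phosphorylation genes (rho = -0.04, permutation p = 0.916 and 0.828) and at 0.04 with the immediate early genes (rho = 0.07, permutation p = 0.829 and 0.729), so neither pair passed there. Within the 7 arrays r was -0.73 with the oxidative phosphorylation genes and 0.59 with the immediate early genes (exact permutation p = 0.0623 and 0.181).

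Of 16 DNA replication genes 4 passed with a positive slope on the mitosis score within the 29 arrays below the T lineage gap, and 13 adjusted over the list alone. Slopes, in log2 per SD of the score, were 0.77 ± 0.15 (SE) for the replication helicase gene MCM2, 0.75 ± 0.13 for FOXM1, a transcription factor of mitotic genes, 0.73 ± 0.12 for the thymidylate synthase gene TYMS, 0.73 ± 0.14 for PRC1, which bundles microtubules of the dividing cell, and 0.57 ± 0.13 for the thymidine kinase gene TK1. The largest positive slope was that of IGFBP2, a binding protein of insulin-like growth factors (0.99 ± 0.21, adjusted p = 0.0217, limma). In the other direction went the adhesion receptor gene CD44 (-1.0 ± 0.23, adjusted p = 0.0426), SERPINB9, an inhibitor of granzyme B (-0.84 ± 0.19), the homing receptor gene CCR7 (-0.82 ± 0.19), MAFG (-0.58 ± 0.12) and STAT3 (-0.51 ± 0.10). No tubulin, microtubule-associated, drug efflux or BCL2 family gene passed, over all genes or adjusted over the list alone. In total 20 genes had a positive and 5 a negative slope past the threshold (limma, adjusted p under 0.05, n = 29). The positive count was 6 without replicate 2 and 13 without replicate 32. The negative count was 8 without replicate 1, 3 without replicate 7, 11, 14, 17, 22, 31 or 34, 2 without replicate 8, 10, 21 or 36 and 1 without replicate 32.

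Over all 36 arrays the mitosis score had 426 genes with a positive and 264 with a negative slope among 10329 tested (limma, adjusted p under 0.05). Those counts hold all 20 positive and 4 of the 5 negative genes of the 29 arrays. They also followed the separation of the 7 arrays: 7 of 20 T lineage genes had positive slopes, such as LCK (1.34 ± 0.33, adjusted p = 0.0115) and MAL (0.97 ± 0.30), and 3 of 7 MHC class II genes negative ones, HLA-DRA among them (-1.26 ± 0.29, adjusted p = 0.00548). Adjusted over the list alone, 13 T lineage genes and 4 MHC class II genes passed, and 0 of either did in the 29 arrays, where the slopes of LCK, MAL and HLA-DRA were 0.45, 0.05 and -0.01 (adjusted p = 0.664, 0.947 and 0.987). SAC3D1 (1.02 ± 0.15), HBEGF (-1.24 ± 0.32), ADM (-1.17 ± 0.28), CCND2 (-1.14 ± 0.21) and BMP2 (-1.14 ± 0.23) passed over the 36 arrays, but in the 29 none did, with slopes of 0.53, -0.37, -0.75, -0.69 and -0.69 (adjusted p = 0.136, 0.41, 0.386, 0.278 and 0.171). TUBB (0.24), TUBA1B (0.23) and TUBG1 (0.44) had positive slopes past the threshold and TUBA4A (-0.51) and ABCB1 (-0.30) negative ones, and none of them passed in the 29 arrays. The counts with the side of the gap as a covariate were 90 and 29, and without replicate 33 they were 145 and 73. Without replicate 26 they were 268 and 138, and the negative count was 168 without replicate 29.

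Of 11 neutrophil granule genes 8 passed with a positive slope on the monocyte score within the 29 arrays, and 10 adjusted over the list alone. Slopes, in log2 per SD of the score, were 1.51 ± 0.13 (SE) for the neutrophil elastase gene ELANE, 1.48 ± 0.12 for the myeloperoxidase gene MPO, 1.22 ± 0.15 for AZU1, 1.30 ± 0.14 for the lactoferrin gene LTF, 0.91 ± 0.12 for LCN2, 1.37 ± 0.11 for S100P and 0.95 ± 0.23 for the proteoglycan gene SRGN. ELANE lay at the floor on 25 of all 36 arrays and LTF on 30. Negative slopes were those of CRMP1 (-0.70 ± 0.17), B3GNT2 (-0.67 ± 0.12), SELENOT (-0.65 ± 0.08), RAP2C (-0.65 ± 0.11), TMEM70 (-0.63 ± 0.10) and EFNB2 (-0.63 ± 0.15). In total 31 genes had a positive and 33 a negative slope in the 29 arrays (limma, adjusted p under 0.05), and 19 and 12 without replicate 25; the negative count was 20 without replicate 24. The 4 arrays above a gap in the neutrophil granule score also had the 4 highest monocyte scores of the 29. In the 25 arrays below that gap no gene passed (limma, 0 of 10332, 744 at an unadjusted p under 0.05), while 5 of the 11 granule genes did so adjusted over the list alone. There, per SD of the score in those arrays, the slope of ELANE was 0.28 ± 0.09 (adjusted p = 0.493), that of MPO 0.39 ± 0.12 (adjusted p = 0.453) and that of S100P 0.31 ± 0.10 (adjusted p = 0.517), while those of SRGN (-0.08), B3GNT2 (0.06) and EFNB2 (0.01) had the other sign. Leaving out arrays by the granule genes lowers the slopes of those genes by construction and narrows the range of the monocyte score, so this fit does not show what the slopes in the 29 arrays rest on.

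Over all 36 arrays, those 4 included, the monocyte score had 61 genes with a positive and 79 with a negative slope among 10334 tested (limma, adjusted p under 0.05), with ELANE at 1.38 ± 0.14, MPO at 1.34 ± 0.12 and SPRY2, an inhibitor of growth factor signalling, at -0.87 ± 0.24. In the 29 arrays SPRY2 did not pass (-0.64 ± 0.20, adjusted p = 0.157). Of the positive genes 27 were shared with the 29 arrays, and of the negative ones 27. No member of the tubulin, microtubule-associated or drug efflux lists passed in the 36 or the 29 arrays. The counts were 28 and 21 without replicate 25, 28 and 20 without replicate 29, and 38 and 39 without replicate 26. The negative count was 46, 48, 51 and 52 without replicates 8, 18, 31 and 32 in turn.

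No gene followed the T lineage score within the 29 arrays below its gap (limma, 0 of 10328 at an adjusted p under 0.05, 822 at an unadjusted p under 0.05), and with robust moderation the numbers were 0 and 800. A single gene passed, with a negative slope, when replicate 14 was left out. Over all 36 arrays no such test was made, because the score split the samples.

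Single genes were tested against 1 technical measure, the scaling factor. POLR3G, a subunit of RNA polymerase III, rose with log2 scaling factor by 0.38 ± 0.07 (SE) per SD of the factor (adjusted p = 0.0154, limma, n = 36), as the only one of 10350 genes, while 1050 had an unadjusted p under 0.05. Its mean log2 signal of 7.06 lay close to the floor, and no gene passed with a floor of 32 or 200 (875 and 1260 at an unadjusted p under 0.05). The count was 0 without replicate 17 and 2 without replicate 13. No list score correlated with log2 scaling factor past the threshold. With the 3'/5' signal ratio of ACTB the B precursor score correlated at r = -0.55 and rho = -0.51 (permutation p = 0.00064 and 0.00153, adjusted p = 0.0356 and 0.0509 over 72 relations; r = -0.50 without the 2 farthest) and the caspase and IAP score at r = 0.52 and rho = 0.49 (permutation p = 0.00099 and 0.00274, adjusted p = 0.0356 and 0.0509; r = 0.49 without the 2 farthest). Just over the threshold lay the immediate early score with the ratios of ACTB (r = -0.47) and GAPDH (r = -0.48). The MHC class II score with that of ACTB (r = -0.50) did so too (adjusted p = 0.0516 each, permutation test). Among the 29 arrays the B precursor value with the ACTB ratio was -0.31 (adjusted p = 0.663), and no list passed for any of the 3 measures.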

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

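The alternatives restricted to the 29 arrays below the T lineage gap, to the 25 of them below the neutrophil granule gap, those with the side of the T lineage gap as a covariate and those without 1 array were chosen after the data were seen; the others were planned. Counts of lists kept within 1.5 times of the reported ones in every alternative, at 16 to 17 for correlated members and 11 to 15 for spread. Signals close to the scaled noise limit what the low genes can show. Except where stated below, the cause of a change was not tested.

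The 12 pairs of lists, of 276 tested, became 19 with a floor of 200, 19 after quantile normalization and 20 with scaling factor as a covariate. With the strict filter 29 of 190 pairs passed. Within the 29 arrays, where fewer arrays entered, 2 of 276 passed. With the gap as a covariate, where all 36 arrays entered, 3 of 300 passed. Leaving out 1 array gave 10 to 28 pairs, with 28 without replicate 2, 21 without replicate 3 and 23 without replicate 14.

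Genes following the mitosis score, 426 positive and 264 negative of 10329 tested, numbered 213 and 95 with the lot batch line as a covariate. The strict filter left 4569 genes to test, of which 647 and 452 passed. The counts were 20 and 5 within the 29 arrays and 90 and 29 with the gap as a covariate. Without 1 array they ranged from 145 to 539 and from 73 to 360; replicate 26 gave 268 and 138, replicate 29 a negative count of 168 and replicate 33 the lowest of both. Within the 29 arrays they ranged from 6 to 28 and from 1 to 8.

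For the monocyte score, the 61 positive and 79 negative genes of 10334 tested became 32 and 49 with a floor of 32. The strict filter left 4573 genes to test, of which 7 and 15 passed. The counts were 31 and 33 within the 29 arrays and 27 and 29 with the T lineage gap as a covariate. Within the 25 below the granule gap they were 0 and 0 (limma, 744 at an unadjusted p under 0.05). The negative count was 38 for the mean of probe sets and 35 after quantile normalization. Without 1 array the counts ranged from 28 to 80 and from 20 to 97, at 28 and 21 for replicate 25, 38 and 39 for replicate 26, 28 and 20 for replicate 29, and with negative counts of 46, 48, 51 and 52 for replicates 8, 18, 31 and 32. Within the 29 arrays the negative count was 20 without replicate 24.

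The 0 genes of the T lineage score stayed at 0 positive in every fit and ranged from 0 to 1 negative without 1 array, with 1 without replicate 14. POLR3G, the 1 gene following scaling factor, was lost, leaving 0, with a floor of 200, a floor of 32, the strict filter, without scaling factors over 50 and within the 29 arrays (limma, with 1260, 875, 337, 657 and 1114 genes at an unadjusted p under 0.05). Its slope within the 29 arrays was 0.38 ± 0.08 (adjusted p = 0.156), against 0.38 ± 0.07 over 36, and 0.07, 0.60 and 0.32 with floors of 200 and 32 and without scaling factors over 50; the strict filter left the gene out. Without 1 array that count ranged from 0 (replicate 17) to 2 (replicate 13), and the negative count from 0 to 0. Within the 25 arrays the slopes of SRGN (0.80 over 36 arrays) and EFNB2 (-0.81) changed sign, at -0.0838 and 0.00997, and neither passed there; that choice of arrays also narrows the range of the score. No paired analysis was possible because the labels put all samples in 1 group.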

Other observations

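The tests in this part were chosen after the data were seen, while quantile normalization and the lot batch line as a covariate were settings chosen beforehand. Within the 29 arrays below the T lineage gap, a large set of genes followed the B precursor score. DNTT, the polymerase that adds bases at joints of antigen receptor genes, had a slope of 1.23 ± 0.24 (SE, log2 per SD), LEF1, a transcription factor of precursor lymphocytes, 1.02 ± 0.14, UQCRC1 of the respiratory chain 0.91 ± 0.21, the adaptor gene LAT2 0.82 ± 0.16 and the cyclin gene CCND3 0.76. In the opposite direction went BCL2A1, an inhibitor of cell death (-1.35 ± 0.20), the adhesion gene FERMT2 (-1.34 ± 0.18), ADM (-1.14 ± 0.25), HLX (-1.04 ± 0.24), FOSL2 (-1.01 ± 0.22), CXCL8 (-0.93 ± 0.25), CEBPD (-0.89 ± 0.15), IER3 (-0.88 ± 0.21) and MAFF (-0.86 ± 0.18). In all 249 genes had a positive and 146 a negative slope among 10333 tested (limma, adjusted p under 0.05), against at most 1 gene in 99 random orders of the arrays. Without replicate 5 the counts were 91 and 41, without replicate 31 they were 164 and 84, and without replicate 25 they were 396 and 188. Of 22 microtubule-associated genes TBCD (0.79 ± 0.20), CKAP5 (0.55) and TBCA (0.38) passed, and 5 adjusted over the list alone. Of 22 oxidative phosphorylation genes 4 passed, all positive, and 6 adjusted over the list alone. No tubulin or drug efflux gene passed over all genes; 3 and 1 did so adjusted over the list alone.

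In the same 29 arrays 11 genes had a positive and 1 a negative slope on the heat shock score (limma, adjusted p under 0.05), with 21 in the highest of 99 random orders. HSPA6, an inducible chaperone, had a slope of 1.35 ± 0.17 (SE), DYNLL1 1.09, CHAC1 0.86, CRIP2 0.72, CACYBP 0.68, ALAS1 0.67, E2F6 0.65, the co-chaperone gene STIP1 0.63, PPP2CB 0.60, MAT2A 0.41, CSNK1A1 0.38 and CDK5RAP3 -0.49. The immediate early score was followed by TRIB1 (0.66), RGCC (0.71), TSC22D1 (0.70), GNA13 (0.66) and CHMP1B (0.46), against at most 4 genes in random orders. For the interferon response and erythroid scores limma called 0 genes, with 636 and 668 at an unadjusted p under 0.05.

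The T lineage score fell in clusters of 29 and 7 arrays. Quantile normalization left a gap of 44.0% of the range with 7 arrays above it, which argues against the authors' scaling. The 3 arrays below the gap whose labels lack the lot batch line had scores up to 0.04, below the lowest of 1.98 above it, which argues against a lot marked by that line as the whole cause. With the line as a covariate the largest gap was 25.8% of the range with 33 arrays above it; all 7 arrays lack the line, so that fit also removes what sets them apart. The 7 arrays below the gap with an ACTB 3'/5' ratio of at least 1.68, the lowest of the 7 above, had scores up to -0.51, which argues against RNA or cDNA length, read as that ratio, as the whole cause. A mixture of B precursor cells with up to 1 normal T cell in 2 cells would lower the B precursor score by at most 1, and 3.45% of the arrays below the gap (1 of 29) would then reach the scores of the 7, so such a mixture is unlikely for the 7 as a set. A larger share of T cells stays open, and a leukaemia of the T lineage is a hypothesis the labels do not address. Apart from the mixture, no biological explanation was tested.

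The probe set used for HUWE1 did not follow the other HUWE1 probe sets, of which only that averaging 10.83 lay well above the floor. The signal of the probe set used for HUWE1 rose with log2 scaling factor (r = 0.65, rho = 0.64, n = 36). With that factor removed it still correlated at 0.84 with RPL39, which argues against scaling as the whole cause. A candidate explanation is that it reads TPT1 transcripts, since its median correlation with the 5 TPT1 probe sets was 0.81 after the same step. The value for RPL39 was as high, while those for RPS29 and a probe set of RPL37A were lower at 0.70 and 0.71, so reading of TPT1 cannot be told apart from a property that bright probe sets share to differing degrees.

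For the genes that followed the B precursor score in the 29 arrays, array scaling is unlikely as the whole cause, since 108 positive and 93 negative genes (201 in all) still passed with log2 scaling factor in the model; the factor removed many of the calls, and a part in them is left open. Dilution by normal myeloid cells would lower the B precursor score as the monocyte score rises. Their r was -0.05 with rho 0.13 (permutation p = 0.805 and 0.491), so no such fall was seen. With 29 arrays a weak negative correlation cannot be told apart from none, so a part of dilution in the pattern is left open. Stress of the cells before lysis stays open: the B precursor and immediate early scores had r = -0.41 and rho = -0.35 (permutation p = 0.0274 and 0.0621), with an adjusted p of 0.312 over 276 pairs and r = -0.17 without the 2 farthest arrays, and the heat shock score gave r = -0.49 and rho = -0.54 (permutation p = 0.00651 and 0.00303, adjusted p = 0.225 and 0.166; r = -0.46 without the 2 farthest). Only 1 of 100 orders of the arrays, the real one, gave as many genes, so chance order of the arrays is unlikely. It is not excluded, since this score was among several tried after the data were seen. Apart from dilution and stress, no biological explanation was tested.

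Random orders of the arrays were also set against the other associations, in each case 100 orders with the real one included. As many genes came from 1 order for the mitosis score over 36 arrays (690 genes, highest other order 103), 2 orders within the 29 arrays (25 genes, highest other 29), 1 order for the monocyte score over 36 arrays (140 genes, highest other 5) and 1 order within the 29 (64 genes, highest other 8). By this count, under 5 in 100 orders, chance order of the arrays is unlikely for these 4 but not excluded. It is least clear for the mitosis score in the 29 arrays, where another order called more genes than the real one. For the scaling factor 4 orders gave at least its 1 gene, with 107 in the highest other, and the count was 0 without replicate 17, so chance is left open there. The highest other order exceeded the real one for the mitosis score in the 29 arrays and, by many times, for the scaling factor; an order that calls so many genes points to structure among the samples, which was not tested. A count of 0 genes for the T lineage score fixes the outcome, at all 100 orders with 2 in the highest other, and says nothing about chance.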
